A study of Macaca mulatta with 10 samples.

How the data were processed

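RNA of liver from 10 rhesus macaques, 5 brain-dead and 5 living-donor control animals, was hybridised to a 1-colour array with 1 array per animal. Per the labels' protocols, livers were recovered after a flush in situ with preservation solution, RNA was extracted with Trizol and purified on columns with DNase, and biotin-labelled RNA was made by amplification. The authors deposited 1 intensity per probe set and array on a linear scale, and per the submitters' processing notes this signal was computed with MAS5, whose version is not given in the sources used here. The deposited signal had a 2% trimmed mean of 1000 on every array, so the arrays had been scaled to a common level. Array medians lay between 175 and 227. Groups, replicate numbers, sex and age were taken from the labels, and the age of 1 brain-dead animal is not given in them. In the main test the replicate numbers only named animals, since the sources used here tie no number to an animal or batch shared by both groups. A batch behind some numbers is not excluded, and the numbers entered the alternatives of a replicate block and of leaving out both arrays numbered 1.

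Signals were put on a log2 scale without a pseudocount and without further normalization. Of 52865 probe sets, the 99 control probe sets were left out of the test, and a probe set was kept when it lay above its array's median on at least 5 of the 10 arrays, which left 26653. Probe sets were named from the platform annotation of 2016 paired with them. Of all probe sets, 24969 had 1 gene symbol, 361 had several and 27535 had none in that table, and only those with 1 symbol were named. Of the gene IDs of the former, 24629 were found in the reference gene table used for current symbols. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), group alone in the model, with Benjamini-Hochberg adjustment over all probe sets kept and a threshold of 0.05. A gene with several probe sets was represented by the one with the highest mean over all arrays. Of 306 changed genes with more than 1 probe set tested, 259 had all others of the same sign and 2 had a probe set past the threshold with the opposite sign. Errors of single genes are standard errors of limma unless called SD, and those of list means are standard errors over animals. The error of a median over genes is the quartile range divided by the square root of the number of genes. Tables were read with data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

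Of 50 gene lists, 48 had at least 5 measured genes and were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Lists of erythroid and platelet genes and of neighbouring tissue had too few measured genes to be tested. Beside camera stood camera with an estimated correlation, fry, and a two-sided exact permutation test of each list's mean per animal, whose smallest p is 0.00794. By that exact test 10 lists had an adjusted p under 0.05, 8 of them also called by camera. Of 1005 list genes 640 were measured, and a gene can stand on several lists. The interaction of group with sex, and the difference between the sexes, were tested with limma on the same values.

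Named genes were the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, up to 3 members of each list, and 14 genes of inflammation and liver function. Of these 14, ALB, CYP7A1 and HMOX1 had no probe set paired with the symbol and are not analysed here, and 1 is not reported here. Groups, tests, gene lists, the rule for named genes and all alternatives not described as added were chosen before the data were examined. Alternatives were quantile normalization, centring on the median, pseudocounts of 16 and 64, no filter or one at the 75th percentile, sex alone or with age in the model, a replicate block, other settings of eBayes, array weights, other thresholds, other list settings, and leaving out each array in turn. Leaving out both arrays numbered 1, lists of lobular zones and a search over symbol families were added after seeing the data.

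The fit was tested on simulated values for the comparison of brain death with control over 26653 probe sets. With 200 changed probe sets, 17.9% of those changed by 1 on the log2 scale were recovered, 79.1% of those changed by 2 and 93.9% of those changed by 3, with 4 false calls among 131. With 1600 changed probe sets these shares were 51.5%, 92.5% and 97.2%, with 49 false calls among 1335. For the gene lists of that comparison over 9835 genes, 4 of 4 lists of 20 genes moved by 0.7 were called by camera with either correlation, and 0 others. Simulated genes are independent, unlike those of a tissue, so these list results do not carry over to correlated genes.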

Results

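Liver of rhesus macaques (Macaca mulatta) was profiled on a 1-colour oligonucleotide array of 52865 probe sets, with 1 array per animal. Livers of 5 brain-dead donors were set against livers of 5 living donors that served as controls. Brain death was induced by gradual inflation of a balloon catheter outside the dura, and blood pressure was held with fluid and with vasopressin, dopamine or both. Brain death lasted 6 h per the sample labels and 5 h per the series' design text, a disagreement left open here. Control animals were ventilated under anaesthesia for 1 h before recovery, so time under ventilation and drugs differ between the groups together with brain death. The control group held 3 females and 2 males, the brain-dead group 2 females and 3 males. Median signals of the 10 arrays lay between 175 and 227, and the number of arrays limits the precision of every value below. Spearman correlations between arrays over all probe sets, those below the filter included, averaged 0.915 within groups and 0.903 between them.

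The comparison of brain-dead with living donors asks how brain death is reflected in liver gene expression before organ recovery. Transcripts of inflammatory signalling were higher in the brain-dead animals, while transcripts of drug metabolism, gluconeogenesis, lipogenesis, fatty acid oxidation and amino acid breakdown were lower. These are among 48 gene lists, of which camera with a preset correlation called 9 higher and 9 lower, and none when the correlation was estimated (camera, Benjamini-Hochberg, lowest adjusted p = 0.199 with an estimated correlation). In each called list the genes that did not pass alone outnumbered those that did, 14 to 8 for targets of NF-kB and 18 to 4 for amino acid genes. STEAP4, a metalloreductase induced in inflamed tissue, was the gene with the largest rise, 50.6-fold (log2 change 5.66 ± 0.57, SE, n = 5 animals per group, limma, Benjamini-Hochberg adjusted p = 0.000584). RTP3, a receptor-transporting protein of liver, fell by 4.02 ± 0.47 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.00180). Of 26653 probe sets tested, 724 rose and 903 fell at a Benjamini-Hochberg adjusted p under 0.05 in limma, and 1344 of these 1627 changed at least 2-fold. They included 666 of 9835 genes measured, 285 higher and 381 lower. The groups did not overlap on any array for 1847 probe sets, 6.93% of those tested, where chance gives 0.794%. The count depended on single arrays. It was 856, 660 and 735 without control animals 1, 2 and 3, and 892, 849 and 680 without brain-dead animals 3, 4 and 5. At 2-fold it was 782, 633, 709, 848, 821 and 633 without the same animals in that order. Both animals numbered 1 lay apart on the second principal component (69.6 and 72.1, the others at most 26.5), and without that pair, a choice made after seeing the data, 674 probe sets changed, 641 of them at least 2-fold.

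Besides STEAP4, the largest rises among genes whose groups do not overlap included TPM2, a tropomyosin of the actin cytoskeleton, at 4.96 ± 0.33. A further 2 probe sets of TPM2 rose, by 5.23 and 4.22, whereas 3 others had changes of -0.84, -0.09 and -0.36 that did not pass the test. SLC13A5, the citrate transporter of the hepatocyte plasma membrane, rose by 4.21 ± 0.41, from a signal of 2244 ± 1787 to 36742 ± 12601 (mean ± SD, n = 5). The calgranulins S100A8 and S100A9, calcium-binding proteins abundant in neutrophils, rose by 3.85 ± 0.74 and 3.54 ± 0.63. The secreted phospholipase PLA2G2A rose by 3.42 ± 0.52 and the siderophore-binding lipocalin LCN2 by 3.20 ± 0.50. ASRGL1, an asparaginase, rose by 3.18 ± 0.47, and the cytokine TNFSF15 by 3.07 ± 0.55. BIRC3, an inhibitor of apoptosis, rose by 2.91 ± 0.33, and of its other probe sets 1 rose by 3.14 and 1 had a change of 0.37 that did not pass. The aggrecan-cleaving protease ADAMTS4 rose by 2.89 ± 0.48, and its other probe set had a change of 0.79 that did not pass the test. ALDH1A3, a retinaldehyde dehydrogenase, rose by 3.53 ± 0.75 from a mean control signal of 135, below the array medians, and by 2.84 with a pseudocount of 64. Its call ended without brain-dead animal 5 and with sex and age in the model (limma, Benjamini-Hochberg adjusted p = 0.0515 and 0.0549, range over its alternatives 0.0147 to 0.0549). The probe sets of S100A9 and LCN2 are of a type that can bind more than 1 transcript.

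Among the largest falls of genes whose groups do not overlap, TSKU, a secreted leucine-rich protein, changed by -3.59 ± 0.52 and SORBS2, an adaptor protein of the cytoskeleton, by -3.15 ± 0.37. ALAS1, the rate-limiting enzyme of haem synthesis in liver, fell by 3.09 ± 0.47 on the log2 scale, from a signal of 19032 ± 5672 to 2795 ± 2182 (mean ± SD, n = 5). The antiproliferative factor TOB1 changed by -3.07 ± 0.42 and the organic anion transporter SLC22A7 by -2.99 ± 0.55. NR1I3, the constitutive androstane receptor that controls drug-metabolising enzymes, changed by -2.72 ± 0.34. LOC702244 (-4.24 ± 0.60), IL36G (-3.01 ± 0.45) and OXER1 (-2.73 ± 0.35) also fell, with mean signals in the brain-dead animals of 48.8, 72.3 and 75.8, below the array medians. The size of change of such dim genes is uncertain, and with a pseudocount of 64 these were -2.75, -2.16 and -2.03. CDT1, a DNA replication licensing factor, changed by -3.12 ± 0.73, or by -2.08 with a pseudocount of 64, its mean signal of 109 ± 110 (SD, n = 5) in the brain-dead animals also lying below the array medians. Its call ended without control animals 1, 2 and 5 and brain-dead animal 5, and with sex and age in the model (limma, Benjamini-Hochberg adjusted p = 0.0659, 0.0696, 0.0533, 0.0661 and 0.0538, range over its alternatives 0.0113 to 0.0696). THRSP, a thyroid hormone-responsive gene of lipogenesis whose groups overlap, had a larger fall than these (-4.46 ± 1.00, and -3.52 with a pseudocount of 64, from a signal of 3800 ± 4075 to 144 ± 175, SD, n = 5). Its call ended without control animals 2 and 3 and brain-dead animals 4 and 5, and with sex and age in the model (limma, Benjamini-Hochberg adjusted p = 0.0563, 0.0557, 0.0546, 0.0619 and 0.0562, range over its alternatives 0.00648 to 0.0619). PDK4, a kinase that restrains pyruvate oxidation, changed by -2.91 ± 0.64. Its call ended without control animals 1, 2 and 3 and without both animals numbered 1 (limma, Benjamini-Hochberg adjusted p = 0.0547, 0.0550, 0.0549 and 0.0602, range over its alternatives 0.0111 to 0.0602).

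**Figure D1:**
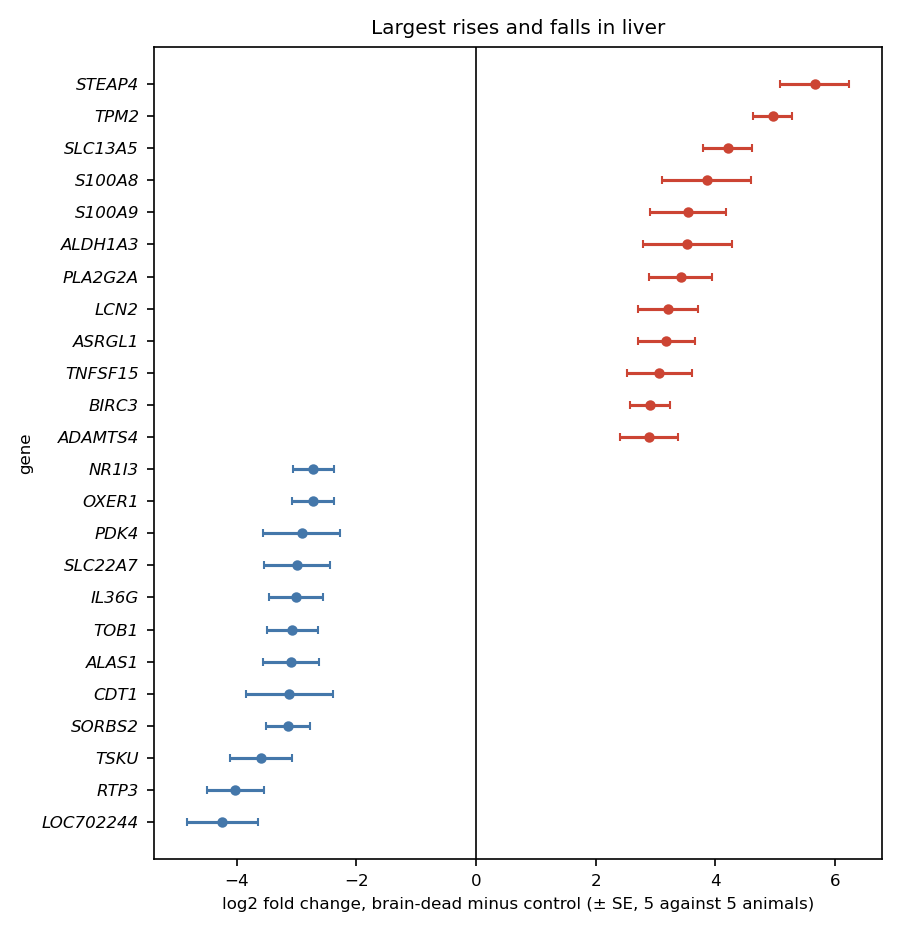
Log2 fold change (brain-dead minus control, horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall among named genes past the threshold whose groups do not overlap, with bars of 1 SE and 5 animals per group. STEAP4 lies furthest to the right at 5.66. LOC702244 (-4.24) and RTP3 (-4.02) lie furthest to the left, in an order that turns with a pseudocount of 64 (-2.75 and -3.50).

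Inflammatory mediators were higher as a group in camera, a call that none of the 3 lists kept with an estimated correlation. Of 22 measured feedback targets of NF-kB, 8 rose, none fell and 14 did not pass the test, and adjusted over the list alone 10 rose and 1 fell. ICAM1, the adhesion molecule that binds leukocyte integrins, rose by 2.46 ± 0.36, and the mitochondrial superoxide dismutase SOD2 by 2.36 ± 0.33, although another SOD2 probe set had a change of -0.03. Of 20 targets of IL-6 and STAT3, 4 rose and none fell (6 and 1 adjusted over the list alone), among them the feedback inhibitor SOCS3 (2.19 ± 0.34) and the kinase PIM1 (1.90 ± 0.23). Of 21 cytokines and chemokines, 6 rose, 1 fell and 14 did not pass (8 and 1 adjusted over the list alone). IL1B rose by 2.25 ± 0.39 and the monocyte chemoattractant CCL2 by 2.33 ± 0.50, while CXCL11 was the member that fell, with a change of -1.68 ± 0.46. CXCL11 was singled out after its values were seen. The camera test placed these lists above other genes (Benjamini-Hochberg adjusted p = 0.000435 for NF-kB, 0.00113 for IL-6 and 0.00610 for cytokines). None passed when the correlation between genes was estimated (camera, Benjamini-Hochberg adjusted p = 0.199, 0.199 and 0.400 with an estimated correlation). The NF-kB list did not pass without genes that other lists share (camera, Benjamini-Hochberg adjusted p = 0.0729, median change 0.057 against 0.74 with all its genes). The cytokine list did not pass with a filter at the 75th percentile of signal (camera, Benjamini-Hochberg adjusted p = 0.116), nor in fry (0.0502). Over their alternatives these p-values ranged from 2.43e-05 to 0.199 for NF-kB and from 0.00105 to 0.400 for cytokines.

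Of the cytokines and adhesion molecules chosen in advance, IL6 rose by 2.36 ± 0.53 (limma, Benjamini-Hochberg adjusted p = 0.0226), while its other probe set, at 1.58, did not pass (0.0594). Its call ended without control animals 1 and 2 and brain-dead animals 3 and 5, without both animals numbered 1, and with sex and age in the model (limma, Benjamini-Hochberg adjusted p = 0.0547, 0.0584, 0.0528, 0.0588, 0.0526 and 0.0558, range over its alternatives 0.0162 to 0.0588). VCAM1, the endothelial ligand of leukocyte VLA-4, fell by 0.83 ± 0.21 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.0374). That call was lost under 12 of 23 alternatives, quantile normalization among them (0.0552, range 0.0134 to 0.0924 for limma with Benjamini-Hochberg adjustment). The arrays whose removal ended it were control animals 1, 2, 3 and 5 (0.0760, 0.0750, 0.0816 and 0.05001, limma, Benjamini-Hochberg) and brain-dead animals 3, 4 and 5 (0.0849, 0.0830 and 0.0924). The neutrophil chemoattractant CXCL8 had a change of 0.90 ± 0.45 and E-selectin (SELE) one of -0.46 ± 0.74, neither past the threshold (limma, Benjamini-Hochberg adjusted p = 0.241 and 0.755). TNF lay below the filter, with a mean signal of 115 ± 84.9 in brain-dead and 140 ± 56.4 in control animals (SD, n = 5). Among 13 endothelial activation and leukocyte adhesion genes 3 rose and 1 fell (3 and 3 adjusted over the list alone), and the list as a whole did not pass (camera, Benjamini-Hochberg adjusted p = 0.922).

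**Figure D2:**
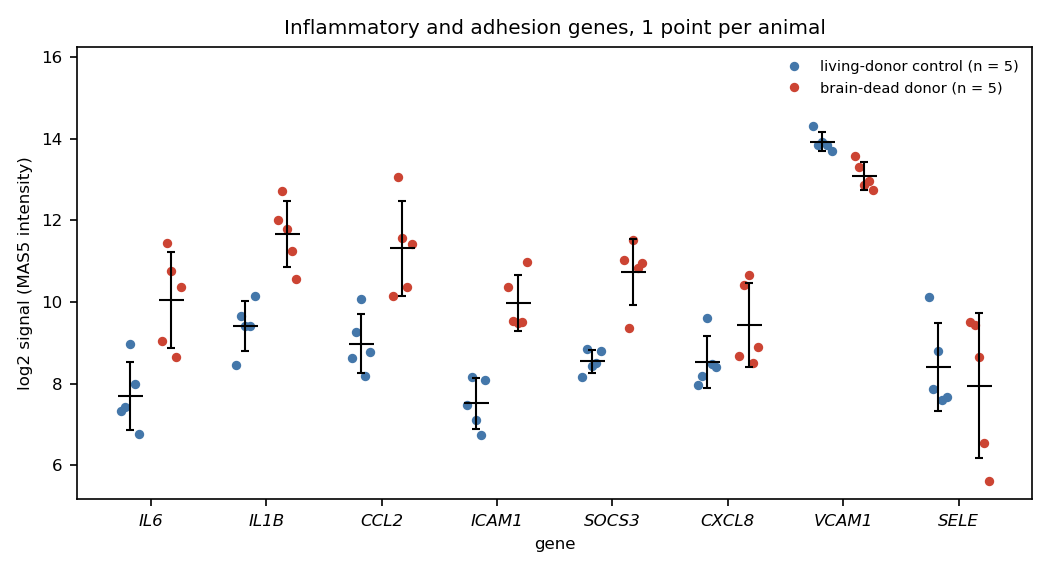
Log2 signal (vertical axis) of IL6, IL1B, CCL2, ICAM1, SOCS3, CXCL8, VCAM1 and SELE, 1 point per animal, with the mean and SD of each group of 5. ICAM1 and SOCS3 are higher in the brain-dead animals by 2.46 and 2.19, while CXCL8 and SELE did not pass the test.

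Genes of antigen processing, cell death, polyamine synthesis and protein folding were also higher as groups in camera, though not with an estimated correlation. Of 15 antigen presentation genes 3 rose and none fell (3 adjusted over the list alone), including the immunoproteasome subunit PSMB8 (1.95 ± 0.41). All 15 had a change above 0, with a median of 0.40 that became 0.187 without control animal 1, 0.601 without control animal 2, 0.23 without brain-dead animal 3, 0.186 without both animals numbered 1 and 0.196 with sex and age in the model. Of 20 genes of apoptosis 2 rose (4 adjusted over the list alone), BIRC3 and the pore-forming BAK1 (1.11 ± 0.21), which act in opposite directions on cell death. The BAK1 call ended without both animals numbered 1 (limma, Benjamini-Hochberg adjusted p = 0.0510, range over its alternatives 0.00752 to 0.0510). Of 10 polyamine and growth response genes 3 rose (3 adjusted over the list alone), the polyamine enzymes ODC1 (1.21 ± 0.26) and SRM (1.15 ± 0.28) and the antizyme inhibitor AZIN1 (1.45 ± 0.38). Each of these 3 calls was lost when some single arrays were left out, ODC1 only without brain-dead animal 5, and also without both animals numbered 1 and with sex and age in the model (limma, Benjamini-Hochberg adjusted p = 0.0501, 0.0543 and 0.0521, range over its alternatives 0.0108 to 0.0543). SRM lost its call without control animals 1, 2 and 3, brain-dead animals 3, 4 and 5, and both animals numbered 1 (limma, Benjamini-Hochberg adjusted p = 0.0671, 0.0732, 0.0700, 0.0514, 0.0760, 0.0800 and 0.0784, range 0.0101 to 0.0800). AZIN1 did so without any array but that of control animal 4 (limma, Benjamini-Hochberg adjusted p from 0.0556 without brain-dead animal 2 to 0.0984 without control animal 3, range over its alternatives 0.00284 to 0.103). Of 16 heat shock and chaperone genes 2 rose (2 adjusted over the list alone), BAG3 (1.27 ± 0.30) and HSPA4 (0.91 ± 0.25). Their calls were lost under 7 and 15 of 23 alternatives (limma, Benjamini-Hochberg adjusted p up to 0.0978 and 0.122). The other probe sets of HSPA4 had changes from 0.31 to 0.94, none past the threshold. Of 14 genes of the unfolded protein response none passed over all genes (2 adjusted over the list alone). The camera adjusted p-values (Benjamini-Hochberg) were 0.00610, 0.00184, 0.00884, 0.0426 and 0.0433 in that order. With an estimated correlation (camera, Benjamini-Hochberg) they were adjusted p = 0.400, 0.400, 0.400, 0.480 and 0.400. The antigen presentation and apoptosis lists did not pass in fry either (Benjamini-Hochberg adjusted p = 0.0502 for each).

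Genes of hepatocyte metabolism and secretion were lower across 8 lists in camera, though not with an estimated correlation. Of 17 lipogenesis and triglyceride genes 6 fell, 1 rose and 10 did not pass (8 and 1 adjusted over the list alone). DGAT2, which catalyses the last step of triglyceride synthesis, fell by 2.11 ± 0.30 on the log2 scale, while the triglyceride lipase PNPLA2, singled out after its values were seen, rose by 1.21 ± 0.25. Of 16 conjugating enzymes and transporters 6 fell (8 adjusted over the list alone), among them the sulfotransferase SULT2A1 (-1.59 ± 0.33). Of 14 genes on the list of cytochrome P450 and phase 1 genes 3 fell (6 fell and 1 rose adjusted over the list alone). Those 3 were the alcohol dehydrogenase ADH4 (-1.44 ± 0.27), FMO5 (-1.21 ± 0.27) and the receptor NR1I3 (-2.72 ± 0.34). No cytochrome P450 of that list passed over all genes. CYP3A4, a major drug-oxidising enzyme, had a change of -0.43 ± 0.21 that did not pass (limma, Benjamini-Hochberg adjusted p = 0.233). Fatty acid oxidation genes fell in 4 of 16 (6 adjusted over the list alone), with EHHADH of peroxisomal oxidation at -2.06 ± 0.42, and the list median of -0.74 became -0.48 without brain-dead animal 5. On the list of gluconeogenesis and glycogen 4 of 15 genes fell (8 adjusted over the list alone). Among them was the insulin receptor substrate IRS1 (-1.38 ± 0.28), a signalling gene and not an enzyme of either pathway. G6PC1 (-1.85 ± 0.50) and SLC37A4 (-1.14 ± 0.31) also fell, but each lost its call under 13 of 23 alternatives (limma, Benjamini-Hochberg adjusted p up to 0.129 and 0.114). Other G6PC1 probe sets had changes of -1.51 and 0.46 that did not pass. PCK1 had a change of -0.41 ± 0.16 that did not pass (limma, Benjamini-Hochberg adjusted p = 0.148). The calls of EHHADH and IRS1 ended without both animals numbered 1 (limma, Benjamini-Hochberg adjusted p = 0.0544 and 0.0553, ranges over their alternatives 0.00531 to 0.0544 and 0.00510 to 0.0553). Amino acid and urea cycle genes fell in 4 of 22 (7 adjusted over the list alone), with the urea cycle enzyme OTC at -1.31 ± 0.25, although another OTC probe set had a change of 0.21. Bile acid genes fell in 4 of 13 (6 adjusted over the list alone), among them AMACR (-1.56 ± 0.35), FGFR4 (-1.25 ± 0.30) and ABCC2 (-0.85 ± 0.22). These 3 lost their calls under 5, 7 and 13 of 23 alternatives (limma, Benjamini-Hochberg adjusted p up to 0.0818, 0.0744 and 0.122). The other probe sets of AMACR (-0.77) and ABCC2 (-0.39) did not pass, while that of FGFR4 (-1.20) did. Of 15 secreted hepatocyte proteins 1 fell (1 adjusted over the list alone), the paraoxonase PON1 (-0.85 ± 0.16), while all 15 had a change below 0 (median -0.42, and -0.23 with quantile normalization). The PON1 call ended without a filter on dim probe sets (limma, Benjamini-Hochberg adjusted p = 0.0659, range 0.00603 to 0.0659). The camera adjusted p-values (Benjamini-Hochberg) of these 8 lists lay between 0.000717 and 0.0159. With an estimated correlation (camera, Benjamini-Hochberg) the lowest was adjusted p = 0.199 for conjugation, followed by 0.315 for gluconeogenesis, 0.372 for bile acids and 0.400 for the others. The lipogenesis and fatty acid oxidation lists did not pass in fry either (Benjamini-Hochberg adjusted p = 0.0502 for each).

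Markers of cell types were measured beside these groups. Of 10 neutrophil markers 3 rose and none fell (4 and 1 adjusted over the list alone), S100A8, S100A9 and the membrane protein VNN2 (2.49 ± 0.48, from a dim control signal of 134), with a median change of 1.09 (camera, Benjamini-Hochberg adjusted p = 0.0108, and adjusted p = 0.400 with an estimated correlation). The VNN2 call ended with sex and age in the model and without both animals numbered 1 (limma, Benjamini-Hochberg adjusted p = 0.0514 and 0.0545, range over its alternatives 0.00815 to 0.0545). Markers of sinusoidal and vascular endothelium had a median change of -0.35, lower as a list (camera, Benjamini-Hochberg adjusted p = 0.0243, and adjusted p = 0.603 with an estimated correlation), with none of 16 past the threshold (0 adjusted over the list alone, 3 at unadjusted p under 0.05 in limma). Hepatocyte identity genes fell in 2 of 12 (3 fell and 1 rose adjusted over the list alone), and the list did not pass in camera (Benjamini-Hochberg adjusted p = 0.194). Its mean per animal was lower by the exact permutation test (change -0.43 ± 0.10, exact, Benjamini-Hochberg adjusted p = 0.0381). The 2 members past the threshold were NR1I3 (-2.72) and CEBPA (-1.23). The median change of the list was -0.41, and 4 of the 12 changes lay above 0. None of 18 macrophage, 12 T and NK cell, 5 B cell, 7 stellate cell and 7 cholangiocyte markers passed over all genes in limma, and the lists did not pass in camera. Adjusted over the list alone, 1 T and NK cell marker rose.

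Of 22 measured genes on the list of positive acute phase proteins, the metalloreductase STEAP4 and LCN2 rose, none fell and 20 did not pass (3 rose and 1 fell adjusted over the list alone). The serum amyloid A genes SAA1 (1.57 ± 0.46) and SAA2 (-0.84 ± 0.23) did not pass (limma, Benjamini-Hochberg adjusted p = 0.0624 and 0.0502), a pair also chosen after its values were seen. The median change of this list was -0.07, its mean 0.45 and its test direction upward, and it did not pass in camera (Benjamini-Hochberg adjusted p = 0.489). Its mean per animal was higher by the exact permutation test (change 0.45 ± 0.09, exact, Benjamini-Hochberg adjusted p = 0.0381). That mean includes the large rises of STEAP4 (5.66) and LCN2 (3.20), while only 9 of the 22 changes lay above 0. Whether it holds without STEAP4 and LCN2 was not tested. Interferon-stimulated genes rose in 3 of 23 (4 adjusted over the list alone), IRF7 by 1.66 ± 0.21 although its other probe set had a change of 0.12, with the list not past the threshold (camera, Benjamini-Hochberg adjusted p = 0.268). Of 18 glucocorticoid-responsive genes 1 rose and 2 fell (3 and 5 adjusted over the list alone), and of 12 clock genes 2 fell (3 fell and 1 rose adjusted over the list alone), including the repressor CRY2 (-1.78 ± 0.33). The growth hormone receptor GHR (-1.71 ± 0.33) was the member of its 12-gene axis that fell (1 fell and 1 rose adjusted over the list alone). In the lists of glycolysis 2 of 17 fell, in cholesterol synthesis 1 of 14, in extracellular matrix 1 of 17, in catecholamine response 1 of 13, in vasoactive genes 1 of 10 and in immediate early genes 1 of 21, ZFP36 (-2.16 ± 0.40). The ZFP36 call ended without both animals numbered 1 (limma, Benjamini-Hochberg adjusted p = 0.0512, range over its alternatives 0.000869 to 0.0512). Coagulation had 1 of 24 higher and metallothioneins 1 of 7, and iron handling, oxidative stress and thyroid hormone genes had 1 higher and 1 lower each. Complement, p53, innate sensing, ribosomal, oxidative phosphorylation, hypoxia and cell cycle genes had none past the threshold over all genes in limma. This holds for the probe set with the highest mean, which represented each gene. Other probe sets of the hypoxia gene HILPDA (1.20) and the p53 target GADD45A (1.02) did pass. A further GADD45A probe set had a change of -1.11 that did not pass. Adjusted over the list alone, the numbers higher and lower were 2 and 3 for glycolysis, 0 and 1 for cholesterol synthesis, 1 and 1 for extracellular matrix and 2 and 3 for catecholamine response. They were 0 and 1 for both vasoactive and immediate early genes, 2 and 2 for coagulation, 1 and 1 for metallothioneins, 1 and 3 for iron handling and 2 and 2 for oxidative stress. For thyroid hormone and innate sensing genes they were 1 and 1, for hypoxia 3 and 2, and 0 for the remaining lists. None of these lists passed in camera with all arrays and the main settings, but 4 did so under an alternative (camera, Benjamini-Hochberg). Interferon genes were higher without brain-dead animal 1 and without both animals numbered 1 (adjusted p = 0.0420 and 0.0127, range 0.0127 to 0.835), and ribosomal genes without brain-dead animal 1 (0.0476, range 0.0476 to 0.960). Coagulation genes were lower without brain-dead animal 1 and at the 75th percentile filter (0.0420 and 0.0329, range 0.0329 to 0.593), and cholesterol synthesis without control animal 4 and with sex and age (0.0219 and 0.0346, range 0.0219 to 0.670). Median, mean and test direction differed in sign for 8 of the 48 lists, none of them called.

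**Figure D3:**
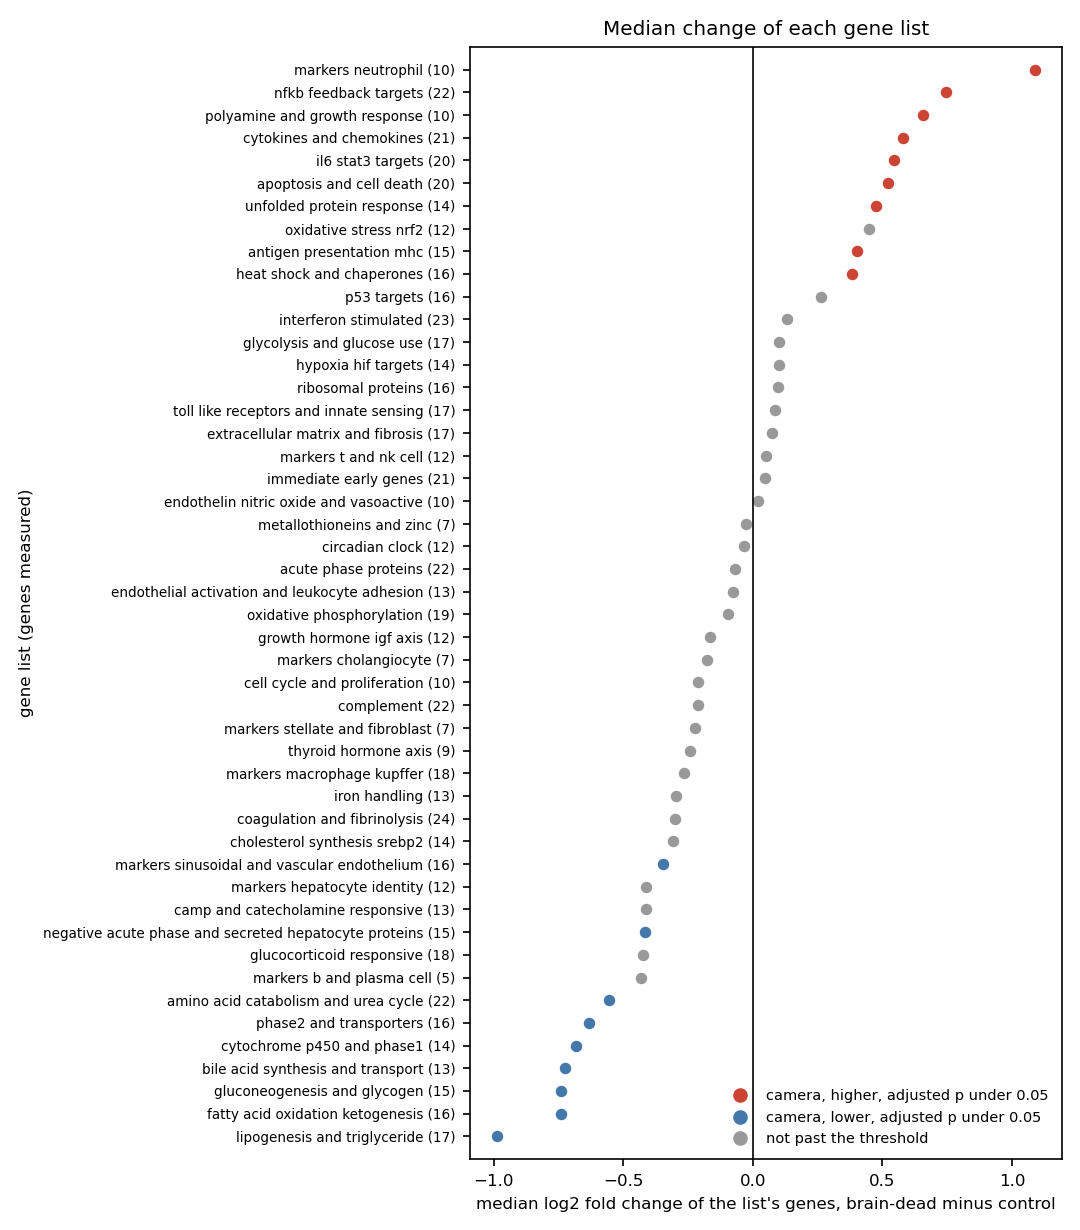
Median log2 fold change (brain-dead minus control, horizontal axis) of the measured genes of each of 48 lists, with the number measured in brackets and colour for the camera call at a Benjamini-Hochberg adjusted p under 0.05. The neutrophil list lies furthest to the right at 1.09 and lipogenesis furthest to the left at -0.99, and 9 lists were called higher and 9 lower.

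In all, camera with a preset correlation of 0.01 called 18 of 48 lists, 9 higher and 9 lower, and fry called 9 of these 18. With an estimated correlation camera called 0, with 5 lists at unadjusted p under 0.05. Other divisions of the arrays into groups of 5 bear on this count, since 5 of 100, the real one included, gave as many lists. The others among these each exchanged 1 animal between the real groups and so largely repeat them. The heat shock, unfolded protein response and endothelial lists were called in 12, 14 and 16 of 24 alternatives. The heat shock call ended without control animals 1, 2 and 5 and brain-dead animals 4 and 5 (camera, Benjamini-Hochberg adjusted p = 0.0683, 0.103, 0.0955, 0.0519 and 0.0847, range over its alternatives 0.0151 to 0.480). It also ended with median centring, sex, sex and age, the replicate block and without both animals numbered 1 (camera, Benjamini-Hochberg adjusted p = 0.0614, 0.0728, 0.0599, 0.0733 and 0.0772), and in fry (0.0985). That of the unfolded protein response ended without control animals 2 and 3 and brain-dead animals 4 and 5 (camera, Benjamini-Hochberg adjusted p = 0.133, 0.0664, 0.0747 and 0.0619, range 0.00410 to 0.400). It also ended with median centring, sex in the model, a filter at the 75th percentile and the mean of a gene's probe sets (camera, Benjamini-Hochberg adjusted p = 0.0616, 0.0728, 0.0865 and 0.0845, median 0.26 against 0.48 in the last), and in fry (0.0502). The endothelial call ended without control animals 3 and 5 and brain-dead animals 2 and 5 (camera, Benjamini-Hochberg adjusted p = 0.0664, 0.0662, 0.0714 and 0.0847, range 0.00348 to 0.603). It also ended with a filter at the 75th percentile and without shared genes (camera, Benjamini-Hochberg adjusted p = 0.0662 and 0.0649), and in fry (0.195).

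Whether the change with brain death differed between females and males was tested with an interaction term. No probe set passed in limma (0 of 26653, 1015 at unadjusted p under 0.05 against 1333 expected by chance). The fit without control animal 4 leaves 1 control male, and that without brain-dead animal 2 leaves 1 brain-dead female. There the interaction was -5.79 for the cell cycle gene GTSE1 and 8.46 for the MHC class I gene MAMU-A, respectively. In these fits each value rests on that 1 animal. With all arrays the MAMU-A interaction was 6.71 ± 1.10 and did not pass. The lowest adjusted p (limma, Benjamini-Hochberg) was 1.00 with all arrays. Females and males of both groups together differed in 0 probe sets in limma, with 3223 at unadjusted p under 0.05 against 1333 expected by chance and a lowest Benjamini-Hochberg adjusted p of 0.144. The metallothionein gene MT1X passed without brain-dead animal 2 (-2.22, limma, Benjamini-Hochberg adjusted p = 0.0150). These 3 genes were chosen after their values were seen. No probe set was paired here with XIST or a Y-linked gene, so the sex labels were not checked against expression.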

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

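The tests of a lower hepatocyte share, of sex and age and of induction in resident cells, and the splits of females and males, were chosen after the result was seen, and the others in this part before it. In 15 of 308 groups of 5 animals, 1 animal lay far from the others, its gap to the nearest exceeding 0.71 of the group's range. Chance alone marks about 1 in 20 groups, 15.4 here, so the number is no pattern by itself.

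Among brain-dead animals, animal 4 was highest for CRY2 (gap 0.887 of the range, log2 signal 10.1 against 8.87 to 9.01 in the others), and animal 1 was highest for FGFR4 (0.813). Animal 5 was lowest for DGAT2 (0.882) and FOLR2 (0.782) and highest for HSPA4 (0.790). Animal 3 was lowest for OSGIN1 (0.758, log2 signal 6.67 against 9.67 to 10.6) and highest for the mean of the immediate early genes (0.758). Animal 4 was highest for the mean of amino acid and urea cycle genes (0.740).

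Among controls, animal 4 was lowest for IRS1 (0.822), animal 2 lowest for ODC1 (0.766) and animal 1 lowest for SOD2 (0.738). For list means, control 3 was lowest in hypoxia genes (0.881) and control 1 highest in hepatocyte identity genes (0.841). Control 2 was highest in T and NK cell markers (0.754) and control 4 lowest in endothelial markers (0.7502).

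Of 125 genes of hepatocyte metabolism on 8 lists, 30 were lower and 1 higher past the threshold in the brain-dead animals, and camera called all 8 lists lower, though none with an estimated correlation (adjusted p = 0.199 to 0.400). A lower share of hepatocyte RNA with larger shares of endothelial, macrophage, stellate, bile duct, T, NK and B cells would raise their markers. The mean change of 65 such markers was -0.23 ± 0.17, below 0 by little more than 1 SE, while hepatocyte identity genes themselves lay lower (-0.43 ± 0.10). Neutrophil markers were left out of the 65 and rose (1.28 ± 0.37), so a lower hepatocyte share through added neutrophils cannot be told apart. Scaling between arrays is argued against by quantile normalization, under which the 125 member genes lay below all genes (-0.57 ± 0.08), with 27 lower and 1 higher past the threshold. Centring on the median shifts all genes of an array alike, so it could not change this gap. This spread, and that given for sex and age below, is over genes that can move together and not over animals. RNA degradation cannot be told apart, because the 3-prime over 5-prime ratios of control transcripts differed by -0.037 ± 0.043, less than that spread, and may miss a loss of shorter-lived transcripts. Sex or age as the whole cause is argued against, since the gap was -0.61 ± 0.07 or larger and all 8 lists stayed called with sex, and sex with age, in the model (26 and 16 genes lower), but brain death itself, drugs and hours under ventilation remain open as untested.

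Of 10 neutrophil markers 3 were higher past the threshold in the brain-dead animals, and the list was called by camera but not with an estimated correlation (adjusted p = 0.400) or by fry (0.0502). More blood of unchanged make-up left in the tissue is argued against by only 4 blood markers, which lay below the neutrophil markers (difference -1.70 ± 0.36). Most of that difference was the neutrophil rise itself (1.28 ± 0.37). The blood markers alone changed by -0.41 ± 0.52, within that spread of 0. Haemoglobin HBA, the most abundant, changed by -0.89 ± 0.69 (signal 7621 against 17717 in controls, limma, Benjamini-Hochberg adjusted p = 0.466). Red cell and platelet genes cannot show whether retained blood held a larger share of neutrophils, so that cannot be told apart. Induction of a few genes that resident cells can also express, as S100A8 and S100A9 can be, cannot be told apart from neutrophils in the tissue. The 5 neutrophil-restricted genes had a mean change of 0.76 ± 0.28, more than 2 SE above 0, but members went both ways (VNN2 2.49 ± 0.48, CAMP 1.19 ± 0.37, CSF3R 0.76 ± 0.34, FPR1 -0.26 ± 0.32, ELANE -0.38 ± 0.40), the mean without VNN2 was 0.33 ± 0.25, and all 5 were dim, under 5 times the typical array median of 202. That limit on dim genes was set after their values were seen, so the result may be read either way, and other differences between the groups remain untested.

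Chance division of the arrays can be excluded for the number of changed probe sets, since of 100 splits into 5 and 5 only 1, the real one, gave as many (1627, highest other 1). The same held at 2-fold (1 of 100, 1344, highest other 1). It could not be excluded for the number of gene lists, where 5 of 100 splits gave as many as the real 18, with a highest other of 21. The other splits that gave as many each exchanged 1 animal between the real groups and so largely repeat them. Splits that exchanged more animals gave at most 14 lists. For probe sets that differ between females and males the real count was 0, which 100 of 100 arrangements reach by construction, so that count decides nothing (highest other 2). At unadjusted p under 0.05, 4 of 100 arrangements, the real one included, gave as many as the real 3223, with a highest other of 3566, but this count was chosen after its value was seen, so chance is not taken as excluded.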

How the results depend on the processing

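Leaving out both arrays numbered 1 was added after seeing the data, and the other alternatives were planned. Of 84 named genes past the threshold 40 stayed past it under every alternative that gave a value, and none turned direction. In 276 of 1912 pairs of such a gene and an alternative the gene was no longer past it, 178 of them when 1 array was left out. Of 431 pairs of a called list and an alternative, 378 were still called the same way, and 53 were no longer called. Of 30 uncalled lists, 4 were called under some alternative. Of 17 named genes not past the threshold, 6 passed it under some alternative. These were TLR6 under 8, SDF2L1 under 7, KLRD1 under 5, HILPDA and MBL2 under 4 each and GADD45A under 3. A gene that a stricter filter removed has no value there. Dim signals near the array median limit what the arrays can show for genes such as CDT1.

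The 1627 changed probe sets became 1056 without a filter, where more probe sets shared the adjustment, and 1035 with sex and age in the model, which has 1 animal fewer. They were 255 at an adjusted p under 0.01 and 3138 under 0.10, by construction. Without both arrays numbered 1 they were 674 (641 at 2-fold), with 2 animals fewer. Over the fits that leave out 1 array they ranged from 660 to 2289, and at 2-fold from 633 to 1837. The 18 lists called became 0 with an estimated correlation and 9 with fry. Female versus male ranged from 0 to 1. Brain death by sex was 0 in every fit that kept at least 2 animals of each sex in each group. Counts of the other fits are not read, and only effect sizes are given from them above. The cause was not tested except where named.

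With the replicate block 3013 probe sets passed. After each group's mean was subtracted from every probe set, correlations between animals of the same number were 0.38, 0.06, 0.13, 0.09 and 0.13. On these values 3 of 10 arrays correlated best with their own number in the other group. Chance alone gives some such matches and their number was not tested against it, so it is no hint of pairing by itself. The animals numbered 1 had the highest of these correlations, a hint from the data and not the design. Both arrays numbered 1 also had the highest mean log2 signal of the spike-in control probe sets (14.05 and 13.88, the others at most 13.77). The numbers are not taken to pair the animals.

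SELE, not past the threshold at -0.46, ranged from -0.85 to 0.13 when 1 array was left out. For 12 uncalled lists the direction of the camera test turned in 52 pairs, none past the threshold, and medians there were as follows. Cell cycle was -0.16 with quantile normalization, and thyroid hormone -0.17 with median centring. Without a filter thyroid hormone was -0.34 and T and NK cells -0.073. At the 75th percentile leukocyte adhesion was -0.14, glycolysis 0.10 and extracellular matrix 0.074. With sex as a covariate immediate early genes were -0.027. With sex and age adhesion was -0.19, immediate early genes -0.034, matrix -0.0067 and T and NK cells -0.16. Without both arrays numbered 1 adhesion was -0.10, vasoactive genes 0.12, thyroid hormone -0.43, cell cycle -0.059, matrix -0.022, T and NK cells -0.16 and cholangiocytes -0.14. With the mean of a gene's probe sets T and NK cells were 0.0499 and cholangiocytes 0.15. Without shared genes adhesion was -0.14, hypoxia 0.10, metallothioneins -0.024, p53 -0.038 and matrix 0.0051. Leaving out 1 array, medians ranged from -0.24 to 0.095 for adhesion, -0.24 to 0.16 for vasoactive genes, -0.082 to 0.22 for immediate early genes and -0.35 to -0.10 for thyroid hormone. They ranged from 0.054 to 0.16 for glycolysis, -0.33 to -0.064 for cell cycle, -0.046 to 0.20 for matrix, -0.14 to 0.22 for T and NK cells and -0.22 to 0.026 for cholangiocytes. The cause was not tested.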

Other observations

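The tests of symbol families and of lobular zones in this part were chosen after the largest changes had been seen. Genes whose symbols share their letters before the first digit were tested as 96 families in an exploratory search. The EIF family is named for translation initiation factors but also holds the kinase EIF2AK3. It had a median change of 0.30 over 34 measured genes, of which 2 rose, EIF4G1 (1.18) and EIF2S2 (0.89). RNA helicases of the DDX group had a median of 0.37 over 23 genes, of which DDX39A rose (1.10), and those of the DHX group 0.36 over 14 genes, of which DHX15 (1.01) and DHX37 (0.97) rose. All 3 families were higher under the deposited scaling (camera, Benjamini-Hochberg adjusted p = 0.0170, 0.0228 and 0.0286), and also with quantile normalization and with median centring. None passed with the correlation estimated (camera, Benjamini-Hochberg adjusted p = 0.866 with an estimated correlation for each). The CYP family, with 3 genes lower and 1 higher of 26 and a median of -0.35, did not pass under the deposited scaling (camera, Benjamini-Hochberg adjusted p = 0.228).

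On the first principal component, which held 32.9% of the variance, the brain-dead animals lay between 27.1 and 98.1 and the controls between -77.8 and -9.65. Within the controls the 2 males (-9.65 and -28.0) lay nearer to the brain-dead animals than the 3 females (-62.2 to -77.8). Whether this position goes with sex was not tested by itself. Between the sexes 0 probe sets passed in limma, but 3223 had an unadjusted p under 0.05 against 1333 expected by chance, a count that 4 of 100 arrangements of the sexes reached, the real one included.

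Some genes that are known to be enriched around the central vein of the liver lobule fell. ALAS1, SLC22A7 and NR1I3, which are among the 12 largest falls of genes whose groups do not overlap, and LECT2 (-2.31), APCDD1 (-2.23) and LGR5 (-2.43, dim in the brain-dead animals at a signal of 114) were noticed because they fell. A list of 17 other central genes was itself lower (mean change -0.38 ± 0.13, exact two-sided permutation p = 0.0397), as were 22 genes of the portal zone (-0.68 ± 0.23, 0.0238), and both means lay below 0 under quantile normalization and median centring too. A larger fall of central than of portal genes as a class can be neither shown nor excluded, since the difference of these means was 0.30 ± 0.21 (exact two-sided permutation p = 0.190) without the 6, a choice that pushes it upward, and -0.29 ± 0.21 (0.238) with them, which pushes it downward. Brain death, drugs and hours under ventilation remain open as untested.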
